A study of Oryza sativa with 12 samples.

How the data were processed

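RNA was taken from rice seeds in water or 300 mM NaCl, and libraries were made from total RNA with a NEBNext Ultra RNA kit, per the labels' protocols. The authors deposited 1 file per library with 1 value per gene ID, 35204 IDs in each. The submitters' processing notes name HISAT2 2.1.0, Bowtie2 2.2.3, HTSeq 0.6.0 and the genome build IRGSP-1.0, with no role or order. The annotation release, the strand setting and the step from counts to the values are not given in the sources used here. Without a stated strand setting, reads of overlapping or antisense genes cannot be told apart, and reads of near-identical copies may have been split or lost.

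The deposited values were treated as FPKM as the authors made them, since no header states the unit. Within a gene the low values are whole multiples of 1 step, the step differs between genes, and column totals ran from 745644 to 829904 FPKM. Whether reads (RPKM) or fragments (FPKM) were counted is not stated, and "read" stands for either. The steps gave each library's total and each ID's implied length, the smallest whole length that fits the values. All 255815 values above 0 of tested IDs (100%) came out whole within 0.003 reads, and the recovered reads made up at least 99.9971% of each library's implied total of 14379728 to 15688593 reads (highest over lowest 1.091). The recovery was tested on 3000 simulated IDs and returned all reads exactly for the 2883 IDs with reads in 3 libraries. Recovered reads were used for depth, counting intervals and the alternatives with voom. Intervals are exact (Poisson for a count, Clopper-Pearson for a share of reads) at 95%, and with no molecular identifiers they and the floor of 3 reads cover counting error only.

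Groups were taken from the sample titles. IDs with at least 1 FPKM in at least 3 libraries (22017) were tested on log2(FPKM + 1), pseudocount 1, with limma 3.58.1 in R 4.3.3. The fit had 1 mean per group over all 12 libraries, 8 residual degrees of freedom, and a variance trend in the empirical Bayes step. Each of the 4 pairwise comparisons and the interaction was adjusted by Benjamini-Hochberg over the tested IDs, and an ID was called at an adjusted p under 0.05. A count test had been planned before the data were examined. It was replaced by this test because the deposited values are FPKM, and it was not run on the recovered reads. On simulated data over 22017 IDs with 200 changed, the test recovered 81% of IDs changed 4-fold and 35% of those changed 2-fold for osmft1 against WT in water, 66% and 34% for osmft1 against WT in salt, 78% and 37% for salt in WT, 78% and 46% for salt in osmft1, and 61% and 17% for the interaction. Of the calls, 4.17% (salt in WT) to 9.91% (osmft1 against WT in salt) were false in that simulation. Its counts varied independently between IDs around a common mean, with no length trend or scaling shift. These rates therefore need not hold for the calls reported below.

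The files do not pair IDs with gene names, and of the IDs only 1 matched the gene table of the assembly ASM3414082v1. The gene lists fixed before the data were examined needed a matching name for each locus and were therefore not used. OsMFT1 was looked up by Os06g0498800, a locus written down from published knowledge before the data were examined. Neither the files nor the table pairs that name with that ID. The rule for named genes, also fixed beforehand, took the largest rises and falls among IDs with an adjusted p under 0.05, a mean of at least 10 in the higher group and no overlap between the libraries of the groups compared. It was applied here to FPKM, without its condition on a gene name, and limited to 2 IDs in each direction. For the interaction it took the smallest p in each direction. Chromosome numbers and the order of loci were read from the Os IDs, which are numbered along each chromosome in the RAP naming system, and no coordinates are given.

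Single values were compared by exact permutation tests, two-sided. Replicates were compared by the chi-square of their recovered reads per degree of freedom, which ran from 7.703 to 23.743, so no library repeats another of its group within sampling noise. The same replicate number did not mark shared libraries, and the main fit had no block. Chosen before the data were examined were another pseudocount, no filter or a filter of 1 CPM in 3 libraries, other scalings, removal of the 50 most abundant IDs, a replicate block, voom with sample weights, fits of 6 libraries, a 2-fold threshold, and leaving out each library. Added after the data were examined were voom without weights, Os loci only, removal of each library's trend on implied length (medians of 20 length bins, with the library's overall median kept), removal of both osmft1 libraries numbered 1, and the sets of salt-lowered and salt-raised IDs. Tables were read with pandas 2.3.3 and numpy 2.4.6 in Python 3.11.15, and plots were drawn with matplotlib 3.10.9.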

Results

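Gene expression was measured by RNA-seq of total RNA from whole rice seeds set to germinate in water or in 300 mM NaCl. The seeds were of Zhonghua 11 (the wild type, WT) and of a knockout of OsMFT1 (osmft1), a gene of the MOTHER OF FT AND TFL1 family, whose members act in seed dormancy and germination. The 4 groups of WT in water, osmft1 in water, WT in salt and osmft1 in salt held 3 libraries each, 12 in all. The labels do not say whether the 3 libraries of a group came from separately grown seed lots, so p-values measure the spread between these libraries, which may be partly technical. The sample titles give no sampling time or germination stage. A difference in stage between groups therefore cannot be told apart from a response to salt or to loss of OsMFT1. Each library listed an FPKM value for 35204 gene IDs, and the steps between low values gave totals of 14379728 to 15688593 counted reads per library. Of these IDs, 22017 reached 1 FPKM in at least 3 libraries and were tested. The files carry no gene names, so genes other than the targeted one appear by ID, with 2 that rose and 2 that fell in each comparison.

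The locus taken as OsMFT1, Os06g0498800, held 1 to 8 reads per library and stayed under 0.7 FPKM in all 12 libraries. In water it stood at 0.28 ± 0.34 FPKM in osmft1 and 0.305 ± 0.255 FPKM in WT (mean ± SD, n = 3), a difference of -0.04 in log2(FPKM + 1) (exact permutation test, two-sided, p = 1). In salt it stood at 0.493 ± 0.276 FPKM in osmft1 and 0.288 ± 0.214 FPKM in WT (SD, n = 3), a difference of 0.21 (exact permutation test, two-sided, p = 0.4). With 3 libraries against 3 the smallest p that this test can give is 0.1. The 95% Poisson interval of the highest count, 8 reads, ran from 3.45 to 15.8 reads, and that of the lowest, 1 read, from 0.0253 to 5.57 reads. A difference between genotypes at this locus was not detectable at this depth, so its level does not check the genotype labels.

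Salt and water separated all libraries on the first principal component of log2(FPKM + 1), which held 59.8% of the variance. The second component held 14.5% and set the osmft1 water libraries (29.9 to 69) apart from the WT water libraries (-51.5 to -28.2). The osmft1 salt library numbered 1 lay nearest to the water libraries among the salt libraries, at 39.2 on the first component against 57.5 to 87.4 for the other salt libraries.

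**Figure D1:**
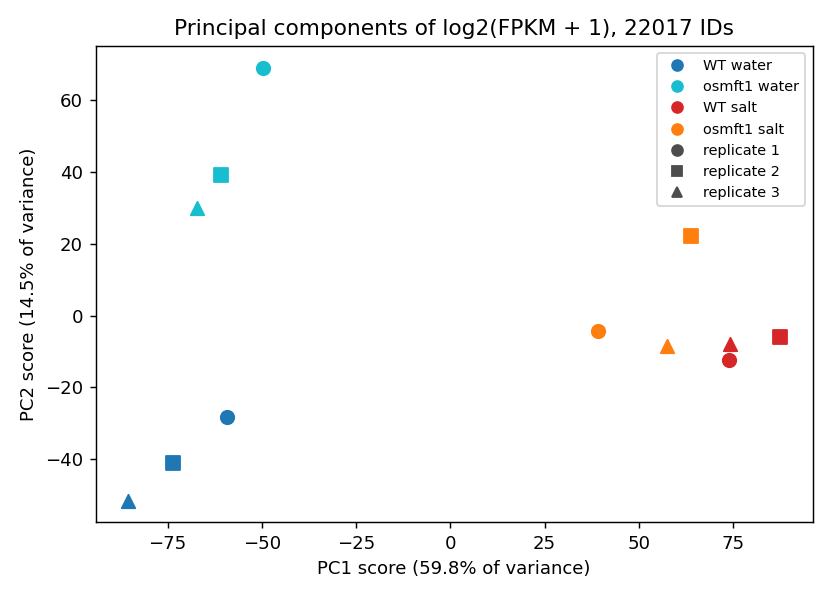
Scores of the 12 libraries on the first 2 principal components of log2(FPKM + 1) of the tested IDs, with the percent of variance on each axis, colour for the group and symbol for the replicate number. All salt libraries have positive and all water libraries negative scores on the first component; osmft1 water replicate 1 has the highest score on the second, 69.

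The comparison of salt with water in WT asked how wild-type seed in 300 mM NaCl differed from wild-type seed in water. Os12g0257600 rose from 0.274 ± 0.194 FPKM in water to 106.8 ± 36.5 FPKM in salt (SD, n = 3), a log2 difference of 6.35 ± 0.25 (SE; limma, adjusted p = 1.03e-07). Os01g0661750 rose from 0.845 ± 1.02 to 98.5 ± 29.9 FPKM, a log2 difference of 5.86 ± 0.47 (SE; limma, adjusted p = 1.94e-06). Os03g0836800 fell from 269.8 ± 111.6 FPKM in water to 0.0449 ± 0.0389 FPKM in salt, a log2 difference of -7.92 ± 0.60 (SE; limma, adjusted p = 1.49e-06). Its 12667 reads in the 3 water libraries stood against 2 reads in the 3 salt libraries, a ratio of 6030 with an exact 95% binomial interval from 1670 to 49800. Os10g0349400 fell from 178.1 ± 102.6 FPKM to 0 reads in every WT salt library, at least 1070-fold lower against a floor of 3 reads over the group (log2 difference -7.28 ± 0.94, SE; limma, adjusted p = 5.46e-05). Log2 differences are on the log2(FPKM + 1) scale, which understates the change of low genes, and the read intervals cover counting error only.

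In all, 12304 IDs (55.9% of those tested) differed between salt and water in WT at an adjusted p under 0.05 in limma, 6101 higher in salt and 6203 lower. Of these, 2546 rose and 2944 fell by at least 2-fold. Of the 20227 Os loci tested 58.9% were called, and of the 1787 short IDs with the prefix EPlOSAG 21.3%. Os loci of different length moved apart with salt in WT, with a median log2 difference of -0.21 in the shortest 25% and 0.25 in the longest 25%. With this trend on length taken out of each library 12161 IDs differed, 10996 of them called in the same direction without that step. The near-even balance then turned, with 6196 higher and 5965 lower. It also turned without the 50 most abundant IDs (6318 higher and 6234 lower).

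The comparison of salt with water in osmft1 asked the same of the knockout. Os12g0257600 led the rise here as well, from 0.407 ± 0.107 FPKM in water to 127.1 ± 26.4 FPKM in salt (SD, n = 3), a log2 difference of 6.49 ± 0.25 (SE; limma, adjusted p = 1.07e-07). Os02g0671100 rose from 7 ± 2.05 to 357.9 ± 89 FPKM, a log2 difference of 5.48 ± 0.34 (SE; limma, adjusted p = 8.69e-07). Os03g0234000 fell from 207.8 ± 83.4 FPKM to 14.5 ± 21.2 FPKM, a log2 difference of -4.69 ± 0.79 (SE; limma, adjusted p = 0.000593). Os10g0349400 fell from 67 ± 38.3 to 5.91 ± 10.2 FPKM, a log2 difference of -4.54 ± 0.94 (SE; limma, adjusted p = 0.00226). The spread of the last 2 loci in salt came from replicate 1, with 38.94 FPKM of Os03g0234000 against 2.727 and 1.898 FPKM in the other salt libraries, and 17.72 FPKM of Os10g0349400 against 0 reads in both others.

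In osmft1, 10132 IDs (46% of those tested) differed between salt and water at an adjusted p under 0.05 in limma, 4514 higher and 5618 lower, and 1831 rose and 1843 fell by at least 2-fold. Median-ratio scaling turned the balance, with 5062 higher and 4917 lower. Across the 22017 IDs, which are not independent replicates, the salt differences in WT and in osmft1 had a Pearson r of 0.751 and a Spearman rho of 0.661. The 2 comparisons share no library. Among the IDs called, 3431 rose in both genotypes, where independent lists would share 1250.8, and 3749 fell in both, where independent lists would share 1582.8. In opposite directions, 129 IDs rose in WT and fell in osmft1, where independent lists would share 1556.8. Another 58 fell in WT and rose in osmft1, where independent lists would share 1271.8. The fit gave each ID the same spread in both comparisons, so the numbers for independent lists are a rough guide.

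**Figure D2:**
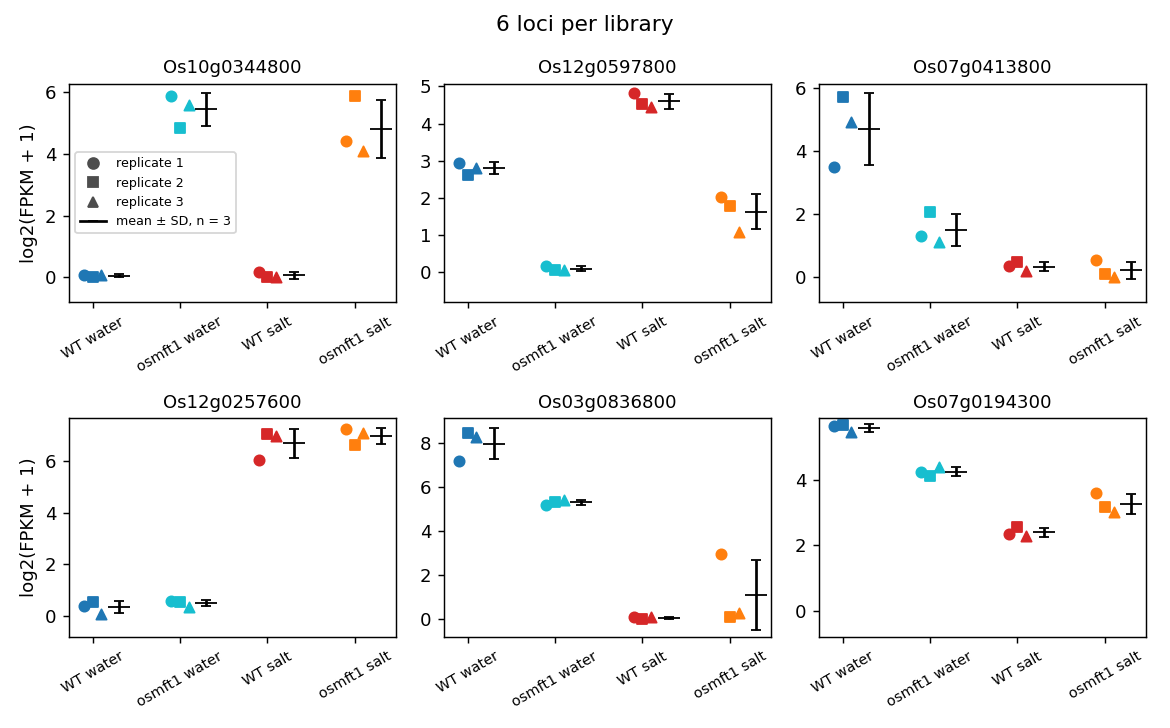
Log2(FPKM + 1) of 6 loci in each of the 12 libraries (symbols by replicate number), with the mean and SD of 3 libraries beside each group. Os10g0344800 is near 0 in all WT libraries and at 16.2 FPKM or more in all osmft1 libraries; Os03g0836800 in osmft1 salt replicate 1 stands at 6.718 FPKM, above 0.068 and 0.203 FPKM in the other osmft1 salt libraries.

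The comparison of osmft1 with WT in water asked how the knockout differed from WT without stress. Os10g0344800 was higher in osmft1, at 44.3 ± 15.3 FPKM against 0.0392 ± 0.034 FPKM in WT (SD, n = 3), a log2 difference of 5.39 ± 0.38 (SE; limma, adjusted p = 7.32e-05). It had 2230 reads in the osmft1 water libraries and 2 in the WT water libraries, a ratio of 1130 (exact 95% binomial interval 311 to 9300). EPlOSAG00000022741, a short ID with an implied length of 26 bases, was higher by 5.19 ± 0.66 (SE; limma, adjusted p = 0.000717), from 80 reads against 2. Os07g0413800 was lower in osmft1, at 1.92 ± 1.08 FPKM against 30.2 ± 20.7 FPKM in WT, a log2 difference of -3.22 ± 0.45 (SE; limma, adjusted p = 0.00123). EPlOSAG00000015368 was lower by a log2 difference of -3.32 ± 0.89 (SE; limma, adjusted p = 0.0178) on 1 read against 23, and it lost the call when either osmft1 water replicate 1 or 2, or WT water replicate 2 or 3, was left out (adjusted p 0.0508 to 0.0704).

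In water 6703 IDs (30.4% of those tested) differed between the genotypes at an adjusted p under 0.05 in limma, 4410 higher in osmft1 and 2293 lower, so that 65.8% were higher. With the libraries scaled by the median ratio to their common mean, 6800 IDs differed and 43.7% of them were higher, and with upper-quartile scaling 57.1% were higher. Median-ratio scaling moved the median log2 difference of all tested IDs from 0.11 to -0.05. At 2-fold or more, 1095 IDs were higher and 498 lower. Os loci of different length moved apart here too: the shortest 25% of loci, with a median implied length of 729 bases, had a median log2 difference of -0.15, and the longest 25%, with a median of 2848.5 bases, one of 0.40. With this length trend taken out of each library, 5677 IDs differed and 71.2% were higher. The count was 3295 without osmft1 water replicate 1, the library with the strongest length trend in its group. It was 3751 without WT water replicate 3 and 4340 without WT water replicate 2.

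**Figure D3:**
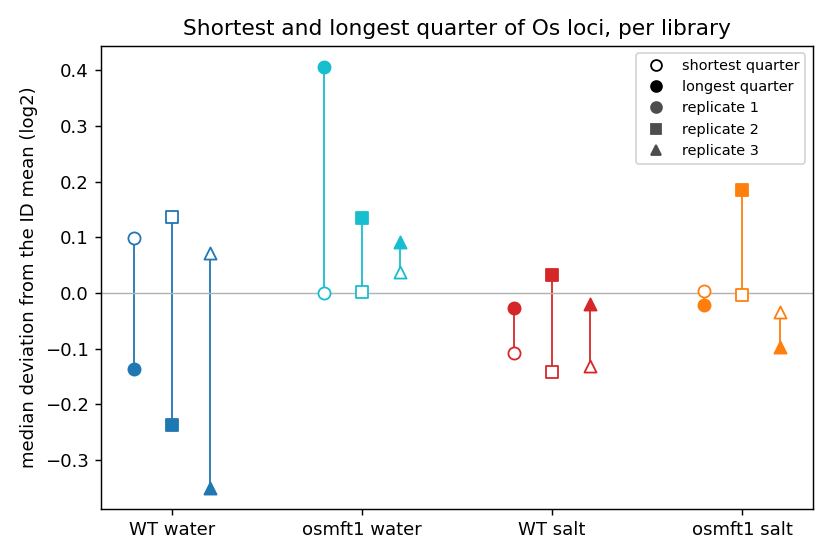
Median deviation of Os loci from their mean over the 12 libraries, in log2 units, for the shortest 25% (open symbols) and the longest 25% (filled symbols) of loci, 1 pair per library. The longest loci lie below the shortest in all 3 WT water libraries (-0.35 to -0.14 against 0.07 to 0.14) and above them in all 3 osmft1 water libraries (0.09 to 0.41 against -0.001 to 0.038).

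The comparison of osmft1 with WT in salt asked how the knockout differed from WT under stress. Os10g0344800 was again higher in osmft1, at 31.4 ± 22.7 FPKM against 0.0419 ± 0.0725 FPKM in WT (SD, n = 3), a log2 difference of 4.74 ± 0.38 (SE; limma, adjusted p = 0.000282) and a read ratio of 755 (exact 95% binomial interval 209 to 6240). EPlOSAG00000022741 was higher by 5.44 ± 0.66 (SE; limma, adjusted p = 0.00161), from 76 reads against 1. Os12g0597800 was lower in osmft1, at 2.21 ± 0.98 FPKM against 23.4 ± 3.65 FPKM, a log2 difference of -2.96 ± 0.22 (SE; limma, adjusted p = 0.000131). EPlOSAG00000022642 was lower by a log2 difference of -3.03 ± 0.54 (SE; limma, adjusted p = 0.0106) on 3 reads against 44, and it was not called in a fit of the 6 salt libraries alone (limma, adjusted p = 0.0892).

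In salt 1199 IDs (5.4% of those tested) differed between the genotypes at an adjusted p under 0.05 in limma, 953 higher in osmft1 and 246 lower, so that 79.5% were higher. Median-ratio scaling gave 729 IDs, of which 57.6% were higher, and upper-quartile scaling 811, of which 64.7% were higher. At 2-fold or more, 279 IDs were higher and 88 lower. The count was 330 in a fit of the 6 salt libraries alone. Leaving out 1 library in turn gave 482 (without WT salt replicate 1) to 883 (without osmft1 salt replicate 2), a fall of over 1.5 times for each library but the last. The genotype differences in water and in salt, which share no library, had a Pearson r of 0.053 and a Spearman rho of -0.043 across the 22017 IDs. Of the IDs called in both, 290 were higher in osmft1 in both treatments, where independent lists would share 190.9, and 126 were lower in both, where independent lists would share 25.6. A further 6 IDs were higher in water and lower in salt, where independent lists would share 49.3. Another 108 were lower in water and higher in salt, near the 99.3 of independent lists. The fit gave each ID the same spread in both comparisons, so the numbers for independent lists are a rough guide.

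The interaction asked at which genes the salt response itself differed between the genotypes. Os07g0194300 fell with salt from 47.7 ± 3.94 to 4.31 ± 0.53 FPKM in WT and from 18.3 ± 1.93 to 8.78 ± 2.12 FPKM in osmft1 (SD, n = 3), a difference of the log2 responses of 2.202 ± 0.218 (SE; limma, adjusted p = 0.00356). Os02g0787000 stood at 38.8 ± 3.94 FPKM in water and 11.3 ± 0.38 FPKM in salt in WT, and at 12.6 ± 1.79 and 12.9 ± 1.02 FPKM in osmft1 (interaction 1.72 ± 0.17, SE; limma, adjusted p = 0.00356). Os07g0693800 had the opposite sign, at 4.01 ± 0.20 FPKM in water and 5.99 ± 0.48 FPKM in salt in WT and at 12.5 ± 1.30 and 5.84 ± 0.34 FPKM in osmft1 (interaction -1.46 ± 0.16, SE; limma, adjusted p = 0.00498). Os04g0403300 stood at 155.9 ± 16.1 and 124.8 ± 5.38 FPKM in WT and at 432.5 ± 26.7 and 158.7 ± 15.1 FPKM in osmft1 (interaction -1.13 ± 0.14, SE; limma, adjusted p = 0.00732).

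The interaction passed an adjusted p under 0.05 in limma at 2872 IDs (13% of those tested), with 1524 positive and 1348 negative values. The balance turned with upper-quartile scaling (1579 and 1867) and without the 50 most abundant IDs (1365 and 1720). It also turned with voom (1613 and 1804), with weighted voom (2101 and 2147) and at the 2-fold threshold (849 and 867). The same held without osmft1 water replicate 3 (1536 and 1650) or osmft1 salt replicate 2 (1841 and 2361). Of the 2872 IDs, 1236 had estimates in the same direction in both genotypes and smaller in osmft1, 210 the same direction and larger in osmft1, and 1426 opposite estimated directions. The salt difference was itself called in both genotypes, in opposite directions, at 187 of them. Os loci of different length moved apart in the interaction too. Its median was 0.254 in the shortest loci (median implied length 729 bases) and -0.374 in the longest (2848.5 bases). With the length trend of each library taken out the count fell to 1864, and 1563 of the 2872 IDs kept their call and direction. The count fell to 317 without the osmft1 libraries numbered 1 in water and in salt. Leaving out 1 library in turn moved it by over 1.5 times for 9 of the 12 libraries of both genotypes, from 752 without osmft1 water replicate 1, 859 without osmft1 salt replicate 3 and 863 without WT water replicate 3 up to 1585 without WT salt replicate 1, while without osmft1 salt replicate 2 it was 4202.

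Loci with a mean salt difference of at least 2-fold over both genotypes formed a set of 2203 lowered IDs and a set of 1976 raised IDs, a choice that uses no difference between the genotypes. The lowered set fell less in osmft1. Its mean log2(FPKM + 1) went from 4.04 ± 0.16 in water to 2.07 ± 0.04 in salt in WT, and from 3.80 ± 0.09 to 2.48 ± 0.25 in osmft1 (SD over 3 libraries). The difference between these responses was 0.664 (exact permutation test of genotype within treatment, 400 relabelings, two-sided, p = 0.01), and 82.9% of the set's IDs had a smaller fall in osmft1. All 3 osmft1 salt libraries lay above all 3 WT salt libraries, at 2.773, 2.320 and 2.363 against 2.060, 2.031 and 2.109, and the highest was replicate 1. Without that library, and with the lowered set chosen anew, the difference was 0.495 (exact permutation test with fewer relabelings, two-sided, p = 0.01). At 57 lowered IDs with at least 20 FPKM in osmft1 water and at most 5% of that level in every WT salt library, osmft1 salt replicate 1 held a median of 20.6% of the osmft1 water level above the WT salt mean, and replicates 2 and 3 held 1.9% and 1.6%. The raised set went from 2.72 ± 0.17 to 4.44 ± 0.16 in WT and from 2.73 ± 0.11 to 4.32 ± 0.03 in osmft1. Its difference of -0.13 did not exceed the spread between libraries (exact permutation test with 400 relabelings, p = 0.405).

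**Figure D4:**
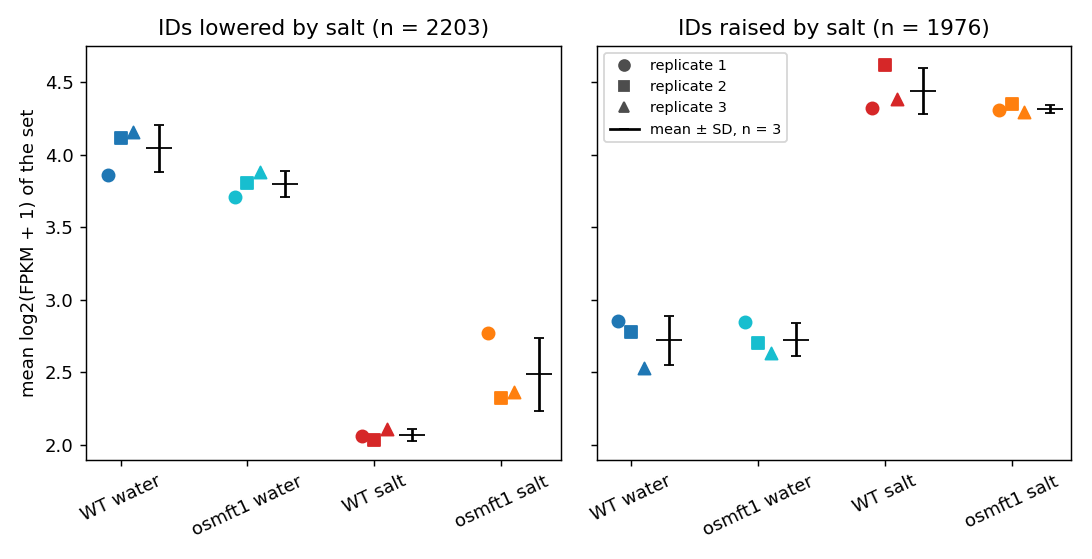
Mean log2(FPKM + 1) of the 2203 IDs lowered and the 1976 IDs raised by salt, per library (symbols by replicate number), with the mean and SD of 3 libraries beside each group. In the lowered set the osmft1 salt libraries lie between 2.320 and 2.773 and the WT salt libraries between 2.031 and 2.109.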

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

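The tests of single libraries, of scaling, of mixed reads, of length as the whole cause and of each library's slope on length were chosen after the results were seen, and the tests of other splits of the libraries before. The test of length as part of a cause was written before its own result. Its threshold, the median log2 difference of 0.11 of all tested IDs in water, was taken from these data.

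The results below differ between the genotypes by the interaction test. It called 2872 IDs at an adjusted p under 0.05 in limma. Of 100 splits of genotype within treatment, drawn from 200, 3 gave as many, the real one included. All 3 were among the 14 drawn splits that kept the genotypes apart in water, so the low share reflects the water libraries and does not exclude chance for the interaction. The highest of the others, 4074, exchanged the genotypes in salt alone and so tested their mean difference over both treatments. The next, 3261, exchanged osmft1 salt replicate 2 with WT salt replicate 3. For the pairwise comparisons the real split was the only 1 of 10 to give as many, and 10 splits are too few for a share under 0.05. The real and highest other counts were 6703 and 2 for genotype in water, 1199 and 5 for genotype in salt, 12304 and 1 for salt in WT, and 10132 and 1 for salt in osmft1. A split that mixes groups adds their difference to the spread. The low counts of the other splits would follow from any difference between the groups, whatever its cause.

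Among the IDs named for the interaction, the log2 responses differed by 2.202 at Os07g0194300, 1.72 at Os02g0787000, -1.46 at Os07g0693800 and -1.13 at Os04g0403300. Of the IDs named in the other comparisons, 4 also passed the interaction test. At Os03g0836800 the responses differed by 3.71 ± 0.85 (SE; limma, adjusted p = 0.0247). Most of this came from its lower level in osmft1 water (38.8 against 269.8 FPKM in WT), since salt left 1 and 3 reads in osmft1 replicates 2 and 3 and at most 1 read per library in WT. Osmft1 salt replicate 1 held 102 reads, and without it the difference was 2.79 ± 0.41 (SE; limma, adjusted p = 0.0171). Os07g0413800 differed by 3.10 ± 0.64 (SE; limma, adjusted p = 0.0189). This too came from its lower level in osmft1 water, with a log2 difference from WT of -3.215 in water and -0.115 in salt. In salt the locus was near 0 in both genotypes, with 8 reads in the osmft1 libraries and 12 in the WT libraries. The short IDs EPlOSAG00000015368 and EPlOSAG00000022642 differed by 4.84 ± 1.26 and -3.03 ± 0.77 (SE; limma, adjusted p = 0.034 and 0.0315), on at most 44 reads per group. Without osmft1 salt replicate 1 the first differed by 5.158 ± 1.365 (SE; limma, adjusted p = 0.0538), a larger difference with a larger SE.

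The 2203 salt-lowered IDs fell less in osmft1, with a mean interaction of 0.664. The tables argue against 1 library or the scaling as the whole cause: the value was 0.495 without osmft1 salt replicate 1 and 0.807 with median-ratio scaling, both with an exact permutation p at or under 0.01. With the length trend of each library taken out the value was 0.588 (exact permutation p = 0.015). Lowered IDs were chosen anew in each of these settings, so the sets need not be the same 2203 IDs. Part of the 0.664 may come from water-state RNA in osmft1 salt replicate 1. At 45 lowered IDs with at least 20 FPKM in osmft1 water and at most 5% of that in the other osmft1 salt libraries, replicate 1 held a share of the water level (median 18%, 5th to 95th percentile 11% to 39.8%), and 2.2% of these IDs lay under 25% of the median share. Measured over the WT salt level at 57 such IDs, the median share was 20.6% in replicate 1, 1.9% in replicate 2 and 1.6% in replicate 3. Water reads or RNA mixed into that library, and seeds in it that had germinated in spite of the salt, would both give such shares and were not told apart. Water-state RNA should also lower the salt-raised set, but no lowering showed there. Replicate 1 stood at a mean log2(FPKM + 1) of 4.308, against 4.346 in replicate 2 and 4.294 in replicate 3. The WT salt libraries ranged from 4.319 to 4.62, and the size of the lowering to look for was not worked out. Another part of the 0.664 lies in the water libraries. The set's mean log2(FPKM + 1) was 3.798 in osmft1 water against 4.043 in WT water (exact permutation p = 0.2). In salt it was 2.485 against 2.067 (exact permutation p = 0.1). Of its IDs, 499 were called lower and 150 higher in osmft1 in water, and 4 lower and 292 higher in salt. The smaller fall thus remained in the other replicates, at 0.495. Whether it is a weaker salt response of osmft1 seeds stays open, since part of the difference lies in the water libraries.

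In water 65.8% of the called IDs were higher in osmft1. The tables argue against osmft1 water replicate 1 as the whole cause (62.8% higher without it). Library scaling cannot be told apart from a true excess: median-ratio scaling centres the libraries on each other, so its 43.7% follows from that centring, and nothing in these data says which scale is right. Gene length as the whole cause is open too, since the 71.2% higher with the length trend taken out was reached with each library's overall median kept, a step that cannot move the balance much. Gene length may set part of the calls: the median difference of the shortest 25% of Os loci minus that of the longest was -0.548, and 4616 of the 6703 called IDs were called in the same direction without the trend.

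The WT water libraries had the lowest slopes of deviation on length, at -0.144 ± 0.041 per doubling of length (SD, n = 3), against 0.082 ± 0.070 in osmft1 water, 0.053 ± 0.013 in WT salt and 0.009 ± 0.055 in osmft1 salt. The slopes did not overlap for genotype in water or for salt in WT (exact permutation p = 0.1 for each, the smallest that 3 against 3 can give), and for genotype in salt and salt in osmft1 the same test gave p = 0.4 and 0.3. RNA integrity, fragment size selection and a true shift in which genes were expressed were not tested.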

How the results depend on the processing

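Of 119 values of results that answer a comparison under the settings other than leaving out 1 library, 98 stayed within 1.5 times the count, the side of the threshold or the spread of the value reported. A count was scored by its size alone, so a turned balance of directions stayed within this bound. Genotype in water with median-ratio scaling did so at 6800 IDs, with 43.7% higher against 65.8%. Of the 6703 IDs called, 5262 were called in the same direction with that scaling. Chosen after the data were examined were the settings without both osmft1 libraries numbered 1, over Os loci only, with the length trend taken out and with voom without weights, and the sets of salt-lowered and salt-raised IDs. A threshold of 2-fold left 1593 IDs for genotype in water, 367 for genotype in salt, 5490 for salt in WT, 3674 for salt in osmft1 and 1716 for the interaction, by its construction. Without both osmft1 libraries numbered 1 these counts were 3060 for genotype in water, 655 for genotype in salt and 317 for the interaction, with fewer libraries, and r was 0.151 for the genotype differences and 0.799 for the salt differences. For genotype in salt, median-ratio scaling gave 729 and the 6 salt libraries alone 330. For the interaction, no filter gave 1247 and the length trend taken out 1864. The cause of these last 4 was not tested. For the salt differences r was 0.703 with a pseudocount of 0.1, 0.782 with the filter on CPM, 0.788 over Os loci only, 0.778 with the length trend taken out and 0.791 over IDs called in either genotype; over IDs called in either treatment r of the genotype differences was 0.120. The OsMFT1 difference in salt was 0.633 with a pseudocount of 0.1, at a few reads per library.

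Leaving out each library in turn gave 3295 to 6554 IDs for genotype in water, 482 to 883 for genotype in salt, 10722 to 11882 for salt in WT, 8448 to 9429 for salt in osmft1 and 752 to 4202 for the interaction. Genotype in water moved by over 1.5 times without osmft1 water replicate 1 (3295) and WT water replicates 2 (4340) and 3 (3751). Genotype in salt did so without every library but osmft1 salt replicate 2, lowest without WT salt replicate 1 (482). The interaction did so at 9 of 12 libraries, lowest without osmft1 water replicate 1 (752). The r of the genotype differences ran from -0.062 to 0.119, below 0 without osmft1 salt replicate 2 (-0.062) or WT water replicate 1 (-0.005), and that of the salt differences from 0.693 to 0.788. The mean interaction of the lowered set ran from 0.495 to 0.790 (exact permutation p 0.005 to 0.015) and that of the raised set from -0.232 to -0.044 (p 0.17 to 0.8). Both sets were chosen anew in each of these fits. Of 394 values for named IDs, 388 kept direction and call and 6 lost the call, all of EPlOSAG00000015368 or EPlOSAG00000022642.

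With the replicate number as a block the counts were 6910, 1145, 12350, 10157 and 3263. The numbers do not pair the libraries: same-numbered libraries correlated between -0.191 and 0.241 in their deviations, and 5 of 12 libraries correlated best with their own number. The planned count-model tests and their scaling factors were not run, since the deposited values are FPKM. The reads recovered from those values were used with voom instead. The gene list tests were not run for want of names. Depth limits IDs with few reads, such as the OsMFT1 locus and the named short IDs.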

Other observations

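The shuffle test and the choice of regions below followed after the positions were seen. The count of IDs on in 1 genotype under other splits was set beforehand. The comparison with salt-changed neighbours of matched number was written before its own result. It took its number of loci and its interval from the genotype loci, so it was not free of these data.

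A small group of IDs was silent in 1 genotype in both treatments. With at least 2 FPKM in all 6 libraries of 1 genotype and under 0.5 FPKM in all 6 of the other, 6 IDs were on in osmft1 and 0 in WT. The 5 Os loci among them lie on 4 chromosomes, and Os10g0344800 is 1 of them. In 1 of 200 splits of genotype within treatment, the real one, there were as many, and the highest of the others was 1. Such splits do not test a chance difference between seed lots, since the libraries of a group may share a lot.

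Of the Os loci, 402 were called in the same direction in osmft1 against WT in water and in salt, 278 higher and 124 lower. They lay next to each other more often than chance, with 20 adjacent pairs changed in the same direction against a mean of 4.78 in 1000 shuffles of the order within chromosomes (permutation p = 0.001, the smallest that 1000 shuffles can give, highest shuffle 14). Across windows of 50 tested loci, the densest was on chromosome 7, from Os07g0203800 to Os07g0217800, where 8 loci were higher in osmft1 in both treatments and 0 lower, with median log2 differences of 3.52 in water and 1.65 in salt (permutation p of the densest window = 0.01). A window on chromosome 10, from Os10g0155100 to Os10g0172600, held 5 higher and 0 lower. No p was computed for that window, so it was not shown to be denser than chance.

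The tables argue against a chance order of loci (permutation p = 0.001 over 1000 shuffles). Co-expression of neighbouring loci, of a kind that is not peculiar to genotype, stays open, since the rows go both ways. The 402 salt loci with as many higher and lower, taken by the largest effect in both genotypes, had 24 adjacent pairs in the same direction, against 20 for the genotype loci (exact 95% Poisson interval 12.2 to 30.9). Taken by the smallest p they had 10, below that interval. In 1000 random draws of 402 from the loci changed at least 2-fold by salt the mean was 8.11, and 0 draws reached 20; all those salt loci were adjacent 1.73 times as often as in shuffles, against 4.19 (2.56 to 6.47) for the genotype loci. Reads shared between near-identical or overlapping neighbours cannot be told apart from separate genes without sequence, and 2 further adjacent pairs went in opposite directions. Linked sequence that differs between the osmft1 line and WT besides the knockout was not tested. The locus taken as OsMFT1 lies on chromosome 6, apart from both windows.

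Called IDs were spread unevenly over chromosomes for salt in WT (permutation p = 0.001 of 1000, adjusted over 5 comparisons 0.005). For genotype in salt the p was 0.021 (adjusted 0.053), and for the other 3 comparisons it was 0.124 to 0.339 (adjusted 0.207 to 0.339). The short EPlOSAG IDs, with 0.149% of all reads and a median implied length of 63 bases, were called at 11.9% for genotype in water, and the Os loci at 32.1%.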
